A study of Homo sapiens with 20 samples.

How the data were processed

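Bulk RNA sequencing of 5 groups was used: naive macrophages, non-eaters, eaters, uneaten SW620 cells and naive SW620 cells. Each group had 2 biological replicates with 2 technical replicates each, 20 libraries in all. Macrophages were human and monocyte-derived. Cells were sorted by fluorescence after co-incubation as the labels state, and the labels do not say whether naive cells passed the sorter. Libraries were made from 200 ng of RNA with a low-input kit and sequenced as paired reads. The labels do not say whether the biological replicates are separate donors or cultures, so p-values measure the spread between these samples and not between people.

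The deposited file holds raw counts per Ensembl gene, whole numbers in 63241 entries with 1 column per library. Per the submitters' processing notes, the build was hg38 and the tools were Trimmomatic 0.39, STAR 2.7.11b and HTSeq, with no role given for each. The strand setting and the annotation release are not given in the sources used here. Gene symbols for 62666 entries (99.1%) and coordinates came from a GENCODE annotation of GRCh38. X-inactivation and Y-linked genes, 525 entries with 0.0166% of counts, were left out. Immunoglobulin and T cell receptor genes were never named.

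Libraries held 6169355 to 13576414 counts. Technical replicates were summed, since they are not independent samples, giving 10 samples. The 10 most abundant genes took 6.12% to 19.9% of a library, and mitochondrially encoded genes 1.05% to 4.01%, with group means of 1.53 ± 0.446% in naive macrophages, 1.65 ± 0.726% in non-eaters, 2.64 ± 0.314% in eaters, 3.82 ± 0.0216% in uneaten and 3.80 ± 0.139% in naive SW620 cells. Over 9296 genes, the spread between technical replicates was 4.54 to 21.0 times counting error (chi-square per degree of freedom), and between biological replicates 17.5 to 65.6 times. No library repeated another, since technical pairs differed beyond counting error. Levels are CPM of all counts, as mean ± SD over 2 samples. Floors cover counting error alone; over the non-eater samples 3 counts are 0.0967 CPM.

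Comparisons, tests, gene lists and the alternatives were fixed before the data were examined, except where the text says otherwise. Genes kept by filterByExpr (19990) were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, robust quasi-likelihood fits over all 5 groups with 5 residual degrees of freedom, two-sided, with Benjamini-Hochberg adjustment at 0.05. Comparisons were eaters against non-eaters and against naive macrophages, non-eaters against naive macrophages, uneaten against naive SW620 cells, and naive SW620 cells against naive macrophages. Also tested was the difference between the non-eater and uneaten effects. Fold changes are log2 with their standard error. Overlap of calls was tested with Fisher's exact test, one-sided. Fits were checked on simulated data with known changes, placed in genes averaging at least 10 CPM over the groups. Of 4-fold changes, 92.4% to 98.5% were recovered, of 2-fold changes 47.8% to 64.2% and of 1.5-fold changes 5.97% to 14.9%. False calls made up 8.55% to 13.8%, above the nominal 5%. Recovery at lower levels was not simulated.

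The share of SW620 RNA was the median, over 372 SW620-specific genes, of a sample's CPM over that of naive SW620 cells. Such genes had at least 20 CPM in naive SW620 cells and under 1/50 of that in naive macrophages. A simulated 30% share was returned as 27.4% and 28.6%. For each replicate number a mixture of non-eater and uneaten SW620 CPM in the measured share was rounded to counts at the eater's depth and tested against eaters with the same edgeR fit (19439 genes). Non-eater and uneaten libraries are in the mixture and in other comparisons, so these share samples.

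Lists of genes, 31 with 568 distinct genes (518 tested), were tested with limma's camera (limma 3.58.1) at a preset correlation of 0.01, and again with the correlation estimated per list. A list needed 5 tested genes, which left 30, or 29 against the mixture. Adjustment ran over the lists of 4 comparisons together. Median and test differed in sign for 2 lists in eaters against non-eaters, 4 in non-eaters, 3 in eaters against naive macrophages, 4 in uneaten cells and 6 against the mixture.

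Named genes followed a rule. Of the called genes with a symbol, at least 10 CPM in the higher group and no overlap of groups, the 8 with the largest rise and the 8 with the largest fall were eligible. For eaters against non-eaters these came from genes that SW620 RNA at naive and uneaten levels cannot raise and from genes below the mixture, plus the 5 largest rises. From each list with a call, up to 4 called genes with at least 5 CPM were eligible, and 13 fixed markers were eligible in every comparison. Genes outside the rule are marked where they are named, and 1 eligible gene is not reported here.

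Alternatives were DESeq2 1.42.0, RLE size factors, no filter and a stricter filter, 20 libraries taken as separate samples, each technical replicate alone, limma-voom with the biological sample as a random effect, a replicate block, a test against a fold of 1.5, the compared groups alone, each sample left out, and other shares and sources for the mixture. With a group reduced to 1 sample, that sample is assumed to vary like the other groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.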

Results

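Human monocyte-derived macrophages and cells of the SW620 colorectal cancer line were profiled alone and after they had been incubated together and sorted. Eaters were the macrophages sorted, per the labels, as having taken up a live SW620 cell. Non-eaters were macrophages of the co-incubation sorted as not having done so, and uneaten SW620 cells were tumor cells left outside. Naive macrophages and naive SW620 cells had no treatment. The 20 libraries came from 2 biological replicates per group, each with 2 technical replicates, and values below are means over the 2 biological replicates with their SD. The first principal component held 90.7% of the variance and separated the cell types, with eaters lying between them. The second held 5.63%.

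The cell types differed in most genes. KRT18 was at 7425 ± 202 CPM (counts scaled to a common library total) in naive SW620 cells and at 30.2 ± 12.5 CPM in naive macrophages. The annotated spans of KRT18 and KRT8 overlap, and without a stated strand setting reads of the 2 genes can be mixed. EPCAM was at 154 ± 7.27 CPM against 0.718 ± 0.413 CPM, and CD24 at 98.1 ± 7.25 CPM against 0.446 ± 0.0285 CPM. LAPTM5 was at 20.4 ± 0.104 CPM in SW620 cells and 4506 ± 537 CPM in macrophages, and PTPRC at 2.53 ± 0.698 CPM against 820 ± 106 CPM. Of 19990 genes tested with edgeR's quasi-likelihood test, 14219 differed (7397 higher and 6822 lower in SW620 cells, Benjamini-Hochberg adjusted p under 0.05). Scaling by library size alone moved the median log2 ratio of all genes from 0.14 to 1.13 and gave 11855 higher and 3985 lower. From these naive cells, 372 genes were taken as specific to SW620 cells and 463 as specific to macrophages, to measure how much RNA of each kind a library held.

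Eater libraries held RNA of both cell types, with macrophage RNA in the majority. The median ratio over the SW620-specific genes gave an SW620 share of 31.6 ± 4.14% in eaters (28.7% and 34.5% in the biological replicates, n = 2). Non-eaters had 0.368 ± 0.0108%, no more than the 0.593 ± 0.225% read in naive macrophages, which is the background of the measure. The macrophage-specific genes gave a macrophage share of 68.7 ± 5.93% in eaters, measured apart from the SW620 share, and the shares added up to 102% and 99.1%. Uneaten SW620 cells carried 0.459 ± 0.0315% macrophage RNA, against 0.398 ± 0.0377% in naive SW620 cells. These are shares of RNA, not of cells.

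**Figure D1:**
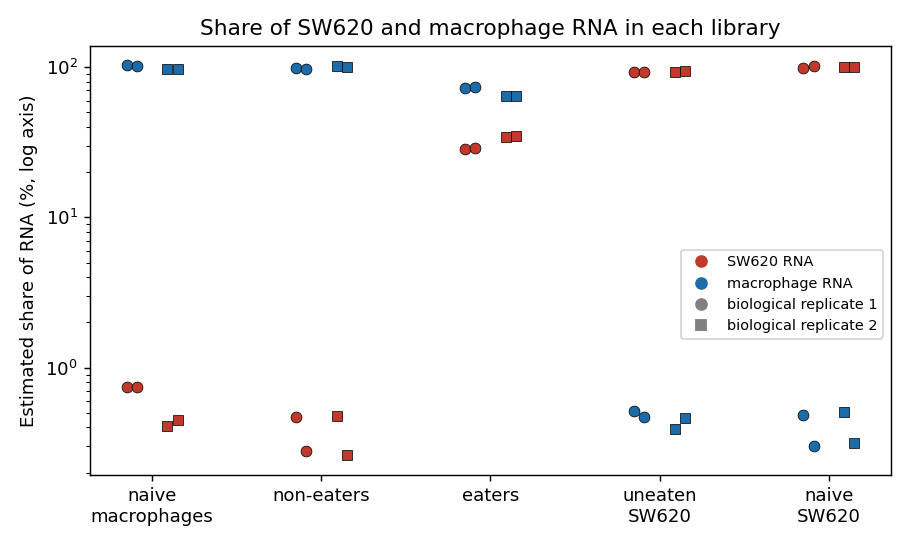
Share of SW620 RNA and of macrophage RNA (percent) in each group, by biological replicate. Only the eater libraries held a large share of both.

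In eaters against non-eaters, the genes that rose most were those of the SW620 line. KRT18 went from 16 ± 2.04 to 2763 ± 196 CPM (log2 fold change 7.03 ± 0.31 SE, adjusted p = 1.69e-07), and CD24 from 0.0385 ± 0.0544 to 29.7 ± 5.96 CPM. CLDN4 (log2 7.33), HNF4A (7.23), the stem-cell receptor LGR5 (7.58), the WNT target AXIN2 (7.21) and EPCAM (5.40 ± 0.33, adjusted p = 1.24e-06) rose too. DSG2 and EFNA1 were listed at 0 in non-eaters and reached 26.2 ± 3.36 and 13.6 ± 1.61 CPM, at least 271-fold and 141-fold above a floor of 3 counts over the group. Macrophage genes were lower: ITGAX fell from 1016 ± 198 to 481 ± 73.1 CPM (log2 −1.47 ± 0.21, adjusted p = 0.000446), FABP4 from 3202 ± 733 to 1501 ± 101 CPM and CTSD from 2605 ± 592 to 1337 ± 318 CPM. ITGAM (log2 −1.12), TREM2 (−1.19) and the phagocytosis checkpoint receptors SIGLEC9 (−1.03) and SIRPA (−1.12) fell as well, while CD14 was not called (0.30 ± 0.38, adjusted p = 0.555). CD47 was lower (log2 −0.89 ± 0.19, adjusted p = 0.00414). The calls of SIRPA and CD47 ended when libraries were scaled by size alone. An SW620 share of 31.6% by itself lowers genes that SW620 cells express little, and the falls in this comparison are not corrected for it. The chemokine CCL22 fell from 2784 ± 1010 to 740 ± 277 CPM (log2 −2.32 ± 0.32, adjusted p = 0.000428).

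Across all genes, 8242 of 19990 differed between eaters and non-eaters, 5175 higher and 3067 lower, with a median log2 change over all genes of 0.12. The split between higher and lower depended on scaling. It was 4656 and 4044 with RLE size factors, 4321 and 3912 with DESeq2, and 7741 and 1031 by library size alone, where the median of all genes was 0.52. Of the 115 named genes called here, 83 stayed called whichever 1 of the 4 samples was left out. Eaters against naive macrophages gave 7772 genes (4924 higher and 2848 lower), or 5047 without eater replicate 2. Library size alone split that comparison into 7550 and 672 and RLE into 4496 and 3731. CCL22 was lower there also, at 2590 ± 809 CPM in naive macrophages (log2 −2.23 ± 0.31, adjusted p = 0.000543). The tight-junction genes CLDN1 and OCLN rose by 7.29 and 6.90 on the log2 scale, and HAMP and GPD1 fell by 1.84 and 2.11.

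Whole gene groups moved with the same split between SW620 and macrophage genes. Among 22 tested genes of colorectal epithelial identity, 18 rose and 0 fell in eaters against non-eaters (20 and 0 adjusted over the list alone, camera adjusted p = 1.46e-31). Their median log2 change was 6.91, or 5.11 with the 3 genes at 0 in non-eaters put at the 3-count floor. It was the one list kept with an estimated correlation (adjusted p = 0.0437). WNT targets rose in 12 of 14 (13 over the list alone, adjusted p = 8.34e-17, 0.0662 with an estimated correlation). Cell-cycle genes rose in 23 of 30, among them AURKB (log2 3.18) and UBE2C (3.03), with adjusted p = 1.5e-05 and 0.686 with an estimated correlation. Lysosome and phagosome genes fell in 26 of 30 and rose in 1 (adjusted p = 3.21e-09), MHC class I presentation fell in 14 of 15 (4.15e-06) and macrophage identity in 13 of 26 (9.22e-05); each had 0.154 with an estimated correlation. Target-cell surface proteins were mixed, 9 higher and 5 lower of 26 (adjusted p = 0.000691, 0.14 with an estimated correlation). T and NK cell markers rose in 2 of 5 (0.000327, 0.14), and both genes, LCK and PRF1, are expressed by naive SW620 cells, at 194 ± 10.2 and 57.2 ± 6.28 CPM.

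Other lists of macrophage genes were lower too, again without correction for the SW620 share, which lowers such genes by itself. Type I interferon genes fell in 14 of 30 (camera adjusted p = 0.000157, 0.327 with an estimated correlation), with OAS1 at log2 −0.97 ± 0.14. The NRF2, heme and iron list (10 lower and 2 higher of 14) had 0.0015 (0.154), and its heme transporter SLC48A1 fell from 193 ± 62 to 64.4 ± 12.3 CPM. Alternative activation (9 lower and 2 higher of 22) had 0.00338 (0.157 with an estimated correlation), autophagy (10 of 18 lower) 0.00344 (0.154) and LXR and PPAR lipid handling (10 lower and 3 higher of 19) 0.00552 (0.311). Phagocytosis checkpoints (11 lower and 1 higher of 16) had 0.0075 (0.299 with an estimated correlation), MHC class II (8 lower and 1 higher of 13) 0.00923 (0.508) and engulfment (11 lower and 5 higher of 29) 0.0103 (0.301). The p53 list (9 lower and 1 higher of 18) had 0.0327 (0.442 with an estimated correlation) and oxidative phosphorylation (6 lower and 1 higher of 21) 0.0381 (0.22). The median of the oxidative phosphorylation list was −0.27 but 0.13 when libraries were scaled by size alone. In all, 18 of 30 tested lists were called with the preset correlation.

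The other 12 lists were not called in eaters against non-eaters. Immediate early genes had 9 of 24 higher and 0 lower (adjusted p = 0.123), with FOSB at 0.435 ± 0.145 CPM in non-eaters and 115 ± 94.3 CPM in eaters. Inflammatory cytokines and NF-kB targets had 6 of 25 higher and 2 lower (0.642). The unfolded protein list had 9 higher (adjusted p = 0.0519), among them TRIB3 (log2 4.45), and heat shock 6 higher (0.0535), among them HSPA4L (3.75). Cholesterol synthesis (4 higher and 6 lower, 0.64), hypoxia and glycolysis (7 and 9, 0.735) and the mesenchymal list (7 and 6, 0.471) were divided. Mitochondrially encoded genes had 0 calls (0.966). Of the lists for other blood and tissue cells, neutrophil markers (2 of 7 lower, 0.0605), dendritic cell markers (0 of 6, 0.624), B cell markers (0.122) and fibroblast and endothelial markers (0.336) were not called. Platelet and erythroid markers had too few expressed genes to test. LUM, from the fibroblast list, rose by 6.62 on the log2 scale and is expressed by naive SW620 cells at 76.1 ± 1 CPM.

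Eater profiles lay close to a mixture computed from the other libraries. Each mixture combined non-eaters and uneaten SW620 cells of the same replicate number in the shares measured above. Across genes, log levels in eaters and mixture had Pearson's r of 0.983 and 0.982 in the replicates, and 96.1% and 95.4% of 8937 and 9104 genes lay within 1.5-fold. Non-eaters alone gave r of 0.841 and 0.812 and 62.6% and 56.4%, and the eater samples of the replicates gave 0.975 and 92.9% against each other. These are correlations across genes, which are not independent replicates. Of the 8242 genes called in eaters against non-eaters, 8161 (99%) had the direction that the mixture gives. Because the mixture contains the non-eaters, these comparisons share control libraries, and part of this figure is built in. In a check chosen after the values were seen, single samples that shared no library gave 95.5% and 95.9%. Naive macrophages in place of eaters gave 65.3% and 63.7% over the same genes. The check used CPM without scaling factors. Its genes were called from these same eater and non-eater libraries, so it does not remove the built-in part.

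**Figure D2:**
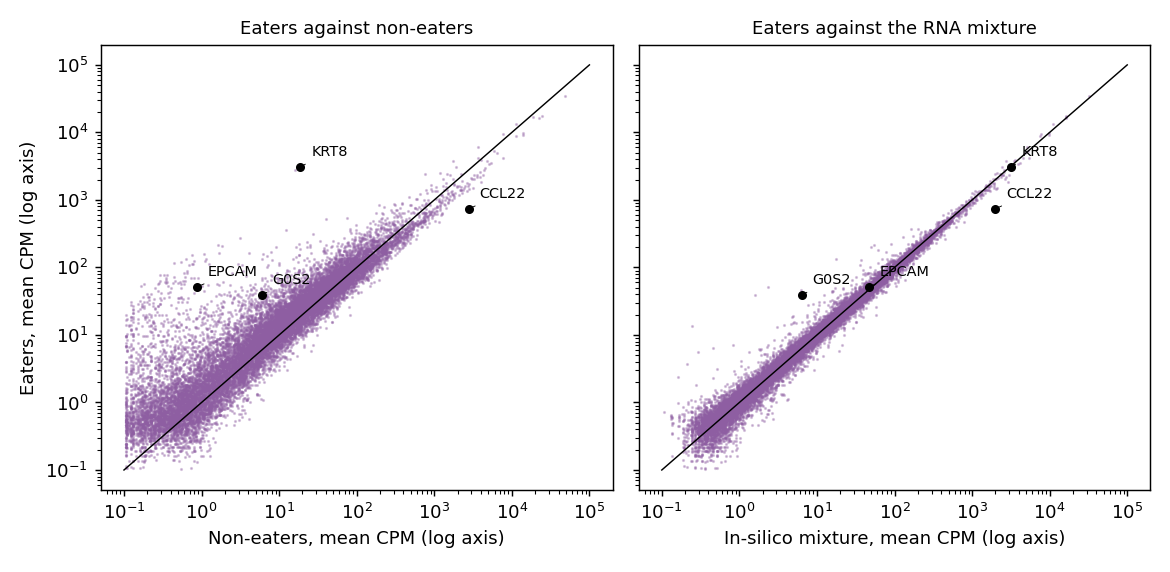
Mean CPM in eaters (vertical) against the computed mixture of non-eater and uneaten SW620 RNA (horizontal), log axes, for 17597 genes above 0.1 CPM in each. Genes lie along the diagonal, with G0S2 above it.

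A single gene, the lipolysis inhibitor G0S2, differed between eaters and the mixture past the threshold in the fit chosen before the values were seen. It was at 39.2 ± 0.91 CPM in eaters, 5.93 ± 2.27 CPM in non-eaters and 7.09 ± 0.0214 CPM in uneaten SW620 cells, and exceeded the mixture by 2.60 ± 0.19 on the log2 scale (adjusted p = 0.00971). Naive macrophages had as much, 35.1 ± 3.13 CPM. With naive macrophages in the mixture in place of non-eaters, edgeR called 0 of 19410 genes, with 453 at an unadjusted p under 0.05; against the non-eater mixture 975 of 19439 were under that value. The call of G0S2 ended without eater replicate 1 and without eater replicate 2, where 0 genes were called. CCL22 was lower than the mixture by 1.47 ± 0.33 on the log2 scale, short of the threshold in that fit (adjusted p = 0.457), though not in every fit tried. Several other fits called more genes than G0S2. Among them were 10 at 1.2 times the share, 86 with naive SW620 cells in the mixture and 204 with libraries as separate samples. A replicate block, a pairing that the labels do not state, gave 116.

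Short-lived response genes stood above the non-eater mixture as groups. Immediate early genes had a median log2 difference of 0.91 (7 of 24 higher adjusted over the list alone, camera adjusted p = 1.5e-20, 0.594 with an estimated correlation). Inflammatory cytokines and NF-kB targets had a median of 0.98 (5 higher adjusted over the list alone, adjusted p = 3.29e-15, 0.594 with an estimated correlation). MHC class II (adjusted p = 0.000289), interferon (0.00252), unfolded protein (0.0377), mitochondrially encoded (0.0377) and macrophage identity genes (0.0427) were higher. Lysosome (0.0183), NRF2 (0.0478) and engulfment genes (0.0478) were lower. With an estimated correlation these ranged from 0.594 to 0.889 and 0 lists were called. Against the mixture with naive macrophages, 5 lists remained past the threshold with the preset correlation, immediate early genes (1.3e-13), interferon (0.000275), mitochondrially encoded genes (0.000545), NF-kB targets (0.00436) and, lower, NRF2 (0.0102), and each had an adjusted p of at least 0.781 with an estimated correlation.

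In eaters against non-eaters, 12 of the 5175 higher genes had lower levels in both SW620 groups than in non-eaters. SW620 RNA at the levels of naive or uneaten cells therefore cannot raise them. Genes that SW620 RNA cannot raise are meant in this sense. The SW620 cells of eater libraries were not measured apart, so a rise in them is not excluded. These 12 were not called against the mixture in the fit chosen before the values were seen, where G0S2 alone passed. With a replicate block, a pairing that the labels do not state, edgeR called ADM (log2 1.785, adjusted p = 0.00212), IFI30 (1.603, 0.00292) and CCL4 (4.354, 0.0325) above the mixture. CCL4L2, CCL3L3, PDE4B, MAP3K8, OLR1, ZC3H12A and PRDM1 were called higher there too, and TNF was not. Their adjusted p is over all 19990 genes and not over this subset. TNF was at 8.56 ± 2.14 CPM in non-eaters and 46.3 ± 33.2 CPM in eaters (log2 2.08 ± 0.66, adjusted p = 0.0326), against 0.129 ± 0.046 CPM in naive SW620 cells. CCL4 went from 3.2 ± 1.59 to 51.1 ± 49.6 CPM (log2 3.60 ± 1.12, adjusted p = 0.0297), ADM from 9.05 ± 0.841 to 27.4 ± 4.95 CPM (1.19 ± 0.33, 0.0154) and IFI30 from 6.67 ± 1.44 to 15.4 ± 0.897 CPM (0.82 ± 0.20, 0.00897). Naive macrophages had levels like those of eaters, with TNF at 41.1 ± 32.7, CCL4 at 43.8 ± 50.6, ADM at 33.1 ± 1.33 and IFI30 at 17.4 ± 0.839 CPM. The others were CCL4L2 and CCL3L3, whose reads are shared with paralogs, and PDE4B, MAP3K8, OLR1, ZC3H12A, PRDM1 and an unnamed gene; the last 4 were chosen after their values were seen. The count was 4 without eater replicate 1 and 5 without non-eater replicate 1. The call of TNF ended without eater replicate 1 and without non-eater replicate 1 or 2 (highest adjusted p = 0.318), those of CCL4 in the same settings (0.271), that of ADM without eater replicate 2 or either non-eater replicate (0.0807) and that of IFI30 without eater replicate 1 or non-eater replicate 1 (0.0704).

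Non-eaters against naive macrophages had 33 called differences, and 30 were falls. G0S2 fell from 35.1 ± 3.13 to 5.93 ± 2.27 CPM (log2 −2.60 ± 0.24, adjusted p = 0.0103), the stress gene DDIT4 from 18.4 ± 2.45 to 2.36 ± 1.37 CPM (−2.93 ± 0.41, 0.0376) and the transcription factor KLF4 from 5.46 ± 0.746 to 0.636 ± 0.356 CPM (−3.05 ± 0.45, 0.0376). The clock gene NR1D1 fell from 15.9 ± 1.3 to 4.36 ± 1.23 CPM (−1.89 ± 0.21, 0.0166). RARG, SGMS2, the lipid-antigen presenting molecule CD1D, SNHG15 and IFI30 fell by 1.41 to 2.10 on the log2 scale. CD47 (adjusted p = 0.714), SIRPA (0.892) and CSF1R (0.759) were not called. Of 19990 genes, 33 differed (3 higher, each an unnamed gene, and 30 lower), with 1798 at an unadjusted p under 0.05. Other tools called more, DESeq2 163 (25 higher and 138 lower), limma-voom 165 (18 and 147) and edgeR with no low-count filter 286 (85 and 201). The count fell to 14 without naive macrophage replicate 1, 13 without replicate 2, 2 without non-eater replicate 1 and 8 without replicate 2. Of the 9 named genes, G0S2 stayed called in each of these but not with the compared groups alone (adjusted p = 0.385), where 0 genes were called; the calls of NR1D1 and SNHG15 ended without non-eater replicate 1 (adjusted p = 0.165 for both), and those of the other 6 in every one. For genes averaging at least 10 CPM, the self-test recovered 59.7% of 2-fold and 7.46% of 1.5-fold simulated changes in this comparison. Most changes of 1.5-fold were thus missed at this number of samples.

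**Figure D3:**
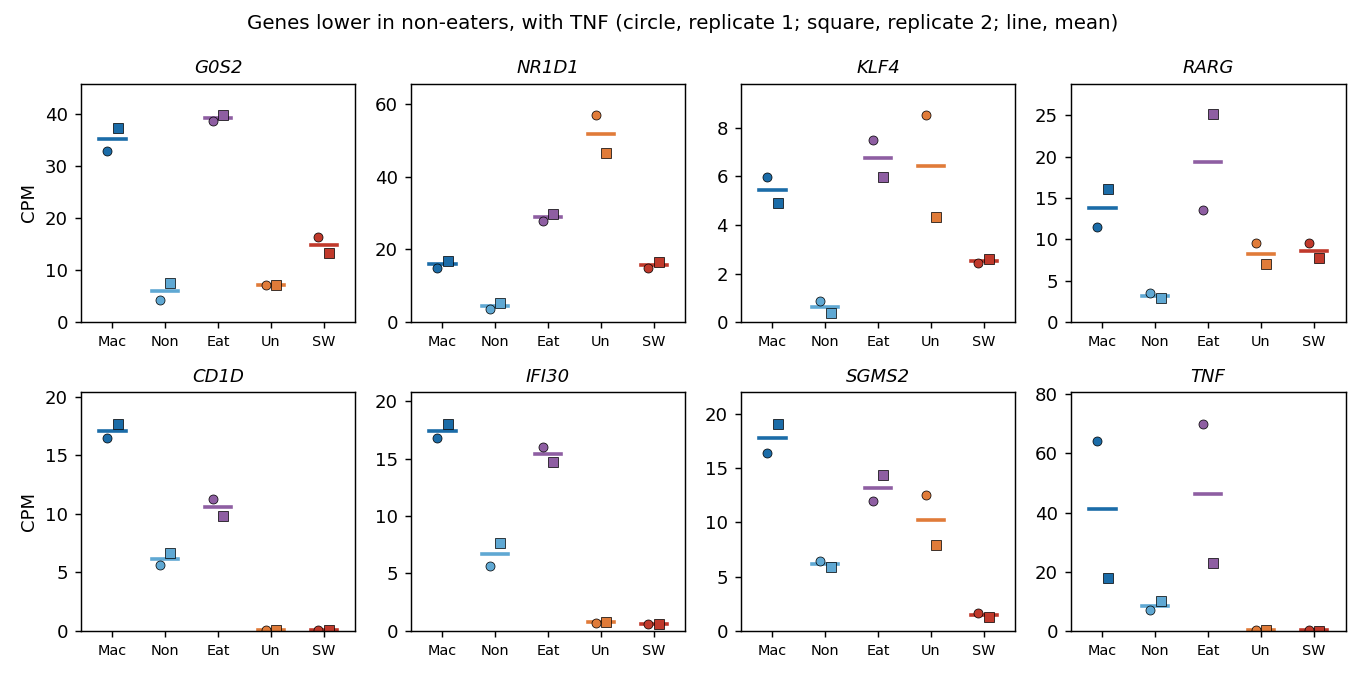
CPM (linear axis from 0) of genes lower in non-eaters, in naive macrophages (Mac), non-eaters (Non), eaters (Eat), uneaten SW620 (Un) and naive SW620 cells (SW); circles are biological replicate 1, squares replicate 2, lines the mean. Levels in non-eaters lay below those in naive macrophages and eaters.

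Response genes were lower in non-eaters as groups, more so in replicate 1. Inflammatory cytokines and NF-kB targets had a median log2 change of −0.95 over 25 genes, with 0 called genes and 0 adjusted over the list alone by edgeR (camera adjusted p = 6.85e-09, 0.301 with an estimated correlation). Immediate early genes had −0.63 over 24 genes, with KLF4 called and 7 lower adjusted over the list alone (1.09e-06, 0.508 with an estimated correlation). By replicate number, the median log2 ratio to naive macrophages was −1.26 and −0.215 for NF-kB targets and −0.629 and −0.151 for immediate early genes. The colorectal epithelial list, near its background in both groups, was lower too (0.000208, 0.205 with an estimated correlation), with 4 of 22 lower adjusted over the list alone. MHC class II (0.0118, 0.522) and the mesenchymal list (0.0327, 0.594), with SNAI1 called, were lower, and B cell markers higher (0.00923, 0.172). With RLE size factors, cholesterol synthesis (0.0428, higher) and WNT targets (0.0479, lower) were called too. With an estimated correlation 0 of 30 lists were called.

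Uneaten SW620 cells differed from naive SW620 cells mostly by higher expression. The scaffold gene AKAP12 rose from 55.3 ± 4.11 to 406 ± 49.4 CPM (log2 2.88 ± 0.19, adjusted p = 0.000506) and CREB5 from 0.943 ± 0.0364 to 18.1 ± 2.22 CPM (4.26 ± 0.40, 0.00203). The NKG2D ligand RAET1L (3.37 ± 0.34, 0.00245), EMP1 (3.26 ± 0.35, 0.00465), the parathyroid hormone-like hormone PTHLH (3.04 ± 0.43, 0.0146) and the EGFR ligand AREG (2.99 ± 0.52, 0.032) rose. KRT17 rose from 0.984 ± 0.364 to 60.3 ± 46.3 CPM and CDKN1A from 8.62 ± 0.209 to 25.3 ± 7.13 CPM. The Notch ligand DLL4 fell from 20.2 ± 3.41 to 5.22 ± 1.94 CPM (−1.93 ± 0.33, 0.0271), PROX1 from 398 ± 2.51 to 179 ± 39.5 CPM (−1.14 ± 0.23, 0.0499) and the WNT inhibitor ZNRF3 from 66 ± 5.29 to 30.5 ± 1.57 CPM (−1.10 ± 0.16, 0.0118). The call of PROX1 ended with RLE size factors. EPCAM (log2 −0.20, adjusted p = 0.814), CD24 (0.02, 0.992) and CD47 (−0.55 ± 0.19, 0.275) were not called.

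Of 19990 genes, 229 differed between uneaten and naive SW620 cells (207 higher and 22 lower), with 2552 at an unadjusted p under 0.05. The count rested on the naive samples: 1 without naive SW620 replicate 2, 6 without naive SW620 replicate 1, 52 without uneaten replicate 1 and 170 without uneaten replicate 2. AKAP12 stayed called in each, and EMP1 in all but the setting without naive SW620 replicate 2 (adjusted p = 0.0652). The calls of CREB5 (highest adjusted p = 0.0652), RAET1L (0.0844) and CDKN1A (0.109) ended without naive SW620 replicate 1 or 2. Those of KRT17 (0.383), PTHLH (0.216) and AREG (0.439) ended in those settings and without uneaten replicate 1, and those of DLL4 (0.383), PROX1 (0.456) and ZNRF3 (0.245) without any 1 sample. In the self-test, 47.8% of 2-fold and 98.5% of 4-fold changes were recovered in this comparison, for genes averaging at least 10 CPM.

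**Figure D4:**
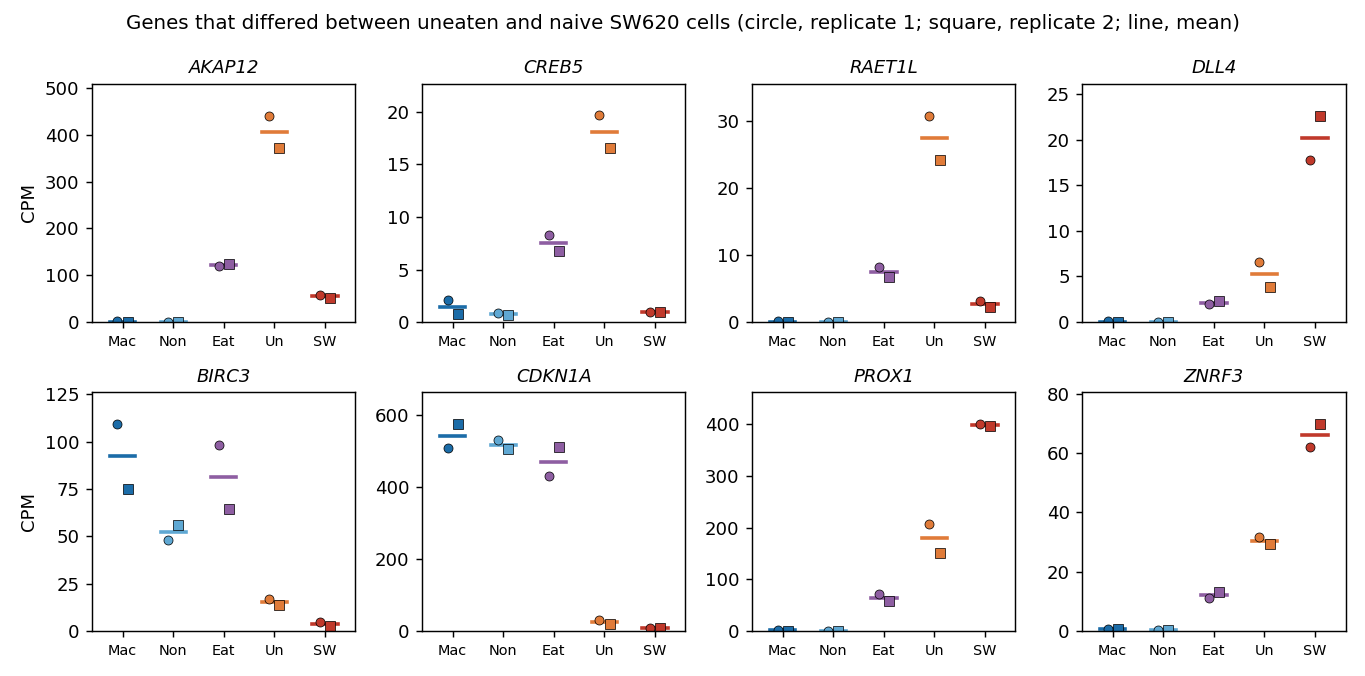
CPM (linear axis from 0) of genes that differed between uneaten (Un) and naive (SW) SW620 cells, with naive macrophages (Mac), non-eaters (Non) and eaters (Eat); circles are biological replicate 1, squares replicate 2, lines the mean. Both uneaten replicates lay on the same side of both naive replicates.

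NF-kB targets had the highest median change of the 30 lists in uneaten SW620 cells. Inflammatory cytokines and NF-kB targets had a median log2 change of 1.32, or 1.22 with genes at 0 put at the floor (6 of 25 higher adjusted over the list alone, camera adjusted p = 2.54e-07, 0.325 with an estimated correlation). BIRC3 rose from 3.5 ± 1.39 to 15.1 ± 2.34 CPM (log2 2.12 ± 0.34, adjusted p = 0.0241, not called without naive SW620 replicate 1 or 2 or uneaten replicate 1). The mesenchymal list (adjusted p = 0.00344, 0.403 with an estimated correlation), autophagy (0.0126, 0.22), immediate early genes (0.0268, 0.814), p53 targets (0.0327, 0.454), with CDKN1A called, and the NRF2 list (0.0388, 0.297) were higher. Cholesterol synthesis (0.0118, 0.319 with an estimated correlation), WNT targets (0.0224, 0.306) and oxidative phosphorylation (0.046, 0.243) were lower, the last not with RLE size factors (0.0686). Adjusted over the list alone, 8 immediate early genes were higher and 1 lower, and 2 WNT targets were higher and 2 lower. With an estimated correlation 0 of 30 lists were called.

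Some genes differed from naive cells in both co-incubated cell types, mostly in opposite directions. NR1D1, lower in non-eaters, rose in uneaten SW620 cells from 15.7 ± 1.15 to 51.7 ± 7.44 CPM. SGMS2, CLCF1, KDM3A, ARID3B, VAMP1, ZC3H12A and CYP2U1-AS1 did likewise, where ZC3H12A, CLCF1, KDM3A, ARID3B, VAMP1 and CYP2U1-AS1 were chosen after their values were seen. These 8 genes were lower in non-eaters and higher in uneaten SW620 cells, against 0.311 expected for lists of this size (Fisher's exact p = 5.56e-10). In edgeR's calls 0 genes moved the same way in both, with 0.0311 expected higher and 0.033 expected lower and with 1798 and 2552 genes at an unadjusted p under 0.05. With DESeq2 it was 3 the same way and 30 in opposite directions, with limma-voom 5 and 36, with no low-count filter 10 and 72, and with 20 libraries as separate samples 11 and 99. The count of 8 genes in opposite directions fell to 0 without naive SW620 replicate 1 or 2 or non-eater replicate 1, to 1 without non-eater replicate 2 or naive macrophage replicate 2, and to 4 without naive macrophage replicate 1. In the settings without non-eater replicate 1 or 2 or naive macrophage replicate 2, 1 gene moved the same way.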

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

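The tests on list genes lower in SW620 cells, on the replicates taken singly, on the non-eater share and on the position of the eaters' SW620 part were chosen only after the result was seen.

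In 1 of 25 group-and-measure checks a sample stood apart. The 10 most abundant genes took 7.464% of counts in 1 naive SW620 library, against 6.24%, 6.115% and 6.261% in the others, which include technical pairs. Chance gives about 1 such gap in 20 checks, and no explanation was tested.

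Differences from naive cells were unlike in the co-incubated cell types. The non-eater effect and the uneaten SW620 effect differed in 188 genes by edgeR's test of the difference itself (24 with the non-eater effect higher, 164 lower, of 19990; Benjamini-Hochberg adjusted). RELB (log2 difference −3.05), BIRC3 (−2.97) and CDKN1A (−1.65) were among them, called higher in uneaten cells and not called in non-eaters; RELB was chosen after its values were seen. The test was not repeated with samples left out. By list, the median difference was −2.62 for inflammatory cytokines and NF-kB targets (camera adjusted p = 1.92e-12, 0.546 with an estimated correlation) and −1.11 for immediate early genes (1.3e-06, 0.665). It was −0.828 for colorectal epithelial identity (0.0284), −0.288 for autophagy (0.0354), −0.244 for the mesenchymal list (0.00159) and 0.284 for cholesterol synthesis (0.00473), each with 0.546 with an estimated correlation. None of the 6 lists was called with an estimated correlation. Cell type, treatment of the naive cells and sorting go together in this contrast.

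Response transcripts were lower in non-eaters as groups, a result of camera that was lost with an estimated correlation. A general loss of short-lived mRNA in this fraction was tested on 425 zinc finger genes, whose transcripts turn over fast. Their median log2 change was −0.104 against 0.0105 for expression-matched lists, a difference of −0.114, and 0% of 10000 matched lists were as low. By replicate number, the median log2 ratio of the zinc finger genes was −0.0648 and −0.0804. The matched lists were drawn from the same samples, so the 0% measures spread between gene lists and not between samples. Within that limit, the loss may contribute. NF-kB targets had a median of −0.95, and the zinc finger value cannot tell how much of it such a loss gives, since turnover was not measured. The same genes had a median of 0.0793 in uneaten against naive SW620 cells. That SW620 RNA at the levels of uneaten cells raises the response genes in eaters was argued against. The 26 list genes lower in naive and uneaten SW620 cells than in non-eaters still exceeded the mixture, with replicate medians of 0.633 and 0.468. The mixture takes its SW620 part from uneaten cells, so it cannot test a rise in the SW620 cells of eater libraries. Whether a single replicate carries the fall cannot be told apart from a fall in both, since 47 list genes had medians of −0.894 and −0.177 and 30 were lower in both. Open are handling and sorting of the naive cells, exposure to SW620 cells without uptake, and differences between donors or cultures, none of which the design separates.

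Eater libraries lay on a mixture of macrophage and SW620 RNA. Free RNA or index exchange between libraries would reach non-eaters too, but their SW620 share was at most 1.31% of that of eaters. SW620 cells attached to macrophages and not inside them remain open: the 3 SW620-specific zinc finger genes differed from the other SW620-specific genes by −0.0226 on average (0.0268 and −0.0721), too few to show a loss of short-lived SW620 transcripts. Eaten and attached cells therefore cannot be told apart by this test, and an ingested cell whose RNA is still intact could give the same values.

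Genes higher in uneaten than in naive SW620 cells were also weighed. Macrophage RNA in the uneaten libraries was argued against, since the measured share of 0.459% supplied the rise of 0 of the 207 genes; for the 51 genes with a higher macrophage level, the median share needed was 21.8%. A feature of the uneaten libraries or of their sort alone was argued against as well. For 62 of these genes with low macrophage levels, the SW620 part of eaters lay at 1.08 and 1.06 in the replicates, on a scale from 0 (naive) to 1 (uneaten), with quartiles of 0.912 to 1.34 and 0.872 to 1.37. A candidate explanation, not tested here, is a response of SW620 cells to co-incubation. Uneaten cells would share it with the SW620 cells of eater libraries, whether eaten or attached. Handling or sorting shared by all co-incubated samples stays open. Non-eaters went through it too, but they are another cell type, so the lower median of their response genes does not decide this.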

How the results depend on the processing

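Scaling by library size alone, the naive-and-naive mixture and the naive-macrophage mixture with a block were tests chosen only after seeing the data. The share of SW620 RNA in eaters stayed at 28.53% to 34.97% under all its alternatives. Genes called in eaters against non-eaters (5702 to 6593 with each sample left out) and between naive cell types stayed within 1.5-fold of the count given above, except 4336 against a fold of 1.5. Of 8543 values of named genes under alternatives, 527 lost the call, 44 gained it and 2 reversed. The other 7970 include genes called in neither setting, for which a change of direction was not counted, and any values without an adjusted p. RFX5, lower in naive SW620 cells than in naive macrophages, was higher by library size alone (log2 0.3768, adjusted p = 0.0703). GPRC5A exceeded a mixture with naive SW620 cells (1.289, adjusted p = 0.0323). The counts below are in the order non-eaters against naive macrophages, uneaten against naive SW620 cells, and genes changed in both cell types. They were 286, 752 and 82 with no low-count filter, 434, 1152 and 110 with 20 libraries as separate samples, 10, 113 and 2 with technical replicate 1 (5 in both cell types with technical replicate 2), and 7, 58 and 1 against a fold of 1.5. With the compared groups alone they were 0, 672 and 0, with DESeq2 163, 462 and 33, and with limma-voom 165, 721 and 41. The 0 with the compared groups alone is edgeR's count of adjusted calls, against 33 with all groups in the fit, where 1798 genes had an unadjusted p under 0.05. The fit with all groups pools the spread of each gene over them. The SD of the log2 difference between biological replicates was 0.407 in naive macrophages and 0.398 in non-eaters. It was 0.285 in uneaten and 0.196 in naive SW620 cells. Pooled p-values for macrophages thus rest partly on the closer SW620 replicates. Leaving out each sample gave 2 to 14, 1 to 170 and 0 to 10. Eaters against naive macrophages had 3890 genes against a fold of 1.5 and 5047 to 6287 with each sample left out. Genes raised in eaters that SW620 RNA cannot raise numbered 29 with 20 libraries, 6 with technical replicate 1, 3 against a fold of 1.5, 39 by library size alone, 21 with limma-voom and 4 to 12 with each sample left out. Against the mixture, 10 genes were called at 1.2 times the share, 86 with naive SW620 cells (83 higher), 0 with naive macrophages, 7 with both naive sources, 204 with libraries as separate samples and 0 to 2 with each sample left out. Lists called with an estimated correlation were 1 in eaters against non-eaters, 0 in non-eaters, 2 in eaters against naive macrophages and 0 in uneaten cells. For these changes the cause was not tested.

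The replicate numbers do not state a pairing. With a replicate block, 152 genes were called in non-eaters, 591 in uneaten cells, 31 in both cell types and 27 that SW620 RNA cannot raise. With the block 116 differed from the mixture (78 higher and 38 lower), CCL22 among them (log2 −1.46, adjusted p = 0.000287), and 2 from the naive-macrophage mixture, ATP2B4 and CCL22, both lower. The block ended the list calls of oxidative phosphorylation in eaters against non-eaters (adjusted p = 0.0507) and in uneaten cells (0.0509) and of the mesenchymal list in non-eaters (0.0953). It added unfolded protein (0.0267), heat shock (0.0223), immediate early (0.0385) and neutrophil genes (0.0242) in eaters against non-eaters, heat shock in non-eaters (0.0371) and unfolded protein in eaters against naive macrophages (0.0443). Across genes, the replicate differences of 2 groups correlated at r = −0.0523 to 0.722, at 0.2 or more in 8 of 10 pairs of groups. Eaters had 0.569 with naive macrophages, 0.478 with naive SW620 cells, 0.318 with non-eaters and 0.312 with uneaten cells; non-eaters had 0.722 with naive macrophages, 0.0818 with uneaten cells and −0.0523 with naive SW620 cells. Shared numbers may therefore mark shared cultures, which the labels do not say. DESeq2 gave no adjusted p for 5039 genes in non-eaters and 2326 in uneaten cells, so its counts cover fewer genes. At this number of samples a change of 1.5-fold was mostly not detectable.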

Other observations

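The clock genes and the comparison of eaters with each mixture by replicate were chosen only after the result was seen.

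Some genes of the circadian clock differed along with NR1D1. Of 15 tested clock genes, 5 were higher in uneaten than in naive SW620 cells and 0 lower by edgeR with Benjamini-Hochberg adjustment: PER1 (log2 2.55 ± 0.29, adjusted p = 0.00419), PER2 (1.88, 0.0221), CRY1 (1.11, 0.0179), NR1D1 (1.73, 0.00419) and BHLHE41 (2.73, 0.0345). These calls ended without naive SW620 replicate 2, which leaves 1 naive sample with no spread of its own. Over 9296 genes the naive SW620 replicates were the closest pair of the 5 groups. The SD of their log2 difference was 0.196, against 0.285 for the uneaten pair. The other 10, among them PER3, CLOCK, BMAL1 and DBP, were not called, and the list had no set test. In non-eaters 1 was lower, NR1D1. The effects differed between the cell types for 6, with PER1 at −4.31 (adjusted p = 0.00364), NR1D1 at −3.62 (0.00183), CRY1 at −1.94 and NR1D2 at −1.63. Sampling times are not given in the sources used here, and the time at which each culture was taken was not tested as an explanation.

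The excess of response genes in eaters was smaller with naive macrophages than with non-eaters in the mixture, most so for NF-kB targets in replicate 1. For NF-kB targets, eaters exceeded the non-eater mixture by a median log2 of 1.24 and 0.64 in the replicates, and the naive-macrophage mixture by 0.202 and 0.475. For immediate early genes the values were 0.75 and 1.05, and 0.423 and 0.93. In replicate 1 the NF-kB difference was thus much smaller against the naive-macrophage mixture. The ratio of non-eaters to naive macrophages was −1.26 in replicate 1 and −0.215 in replicate 2. For TNF and CCL4, chosen for differing between replicates, non-eaters were low in both, at 7.04 and 10.1 CPM and at 4.33 and 2.08 CPM. Naive macrophages were higher in replicate 1, at 64.3 against 18 CPM for TNF and 79.6 against 8.03 CPM for CCL4. Eaters were higher there too, at 69.8 against 22.8 CPM and 86.2 against 16 CPM.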
